A study of Mus musculus with 12 samples.

How the data were processed

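RNA of TRAMP-C mouse prostate tumour cells was measured on 12 Illumina Mouse-6 BeadChip arrays. Per the labels, cells were transfected by nucleofection with empty vector, FOXA2, HIF-1a or both, placed 48 h later in normoxia or 1% oxygen for 12 h, and 500 ng of total RNA was amplified, biotin-labelled and stained with Cy3. The 8 groups, 4 transfections at 2 oxygen levels, were taken from the sample labels. Each hypoxia group held 2 arrays and each normoxia group 1.

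The authors deposited a table of probe intensity on a linear scale, not normalized, for 45281 probes. The software that made it is not given in the sources used here. Beside each intensity the authors deposited a detection p-value, whose values run in equal steps. The authors also deposited a processed table of linear intensity for 26415 probes, which were exactly the probes with a detection p-value under 0.1 on at least 1 array. Its columns followed the non-normalized intensities of their own array with r of 0.997258 to 0.999976 and had medians of 86.075 to 86.2083, as quantile normalization gives. Its exact background correction and normalization stay unknown, and it was used only as an alternative. Of the columns of per-sample values, 0 were unused.

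Intensities were corrected for background with neqc of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values and an offset of 16, then quantile normalized between the 12 arrays and taken to log2. Probes with a detection p-value under 0.01 on at least 2 arrays were kept, 17436 in all. Genes were named from the platform annotation: 14981 of these probes had 1 gene symbol, 5 several and 2450 none here. Of the processed-table probes 21576 had 1 symbol, 11 several and 4828 none, and 21542 were matched by Entrez ID to the RefSeq gene table of GRCm38.p6, with 0 symbols updated. No probe coordinates were used. Each gene was represented by its detected probe of highest mean intensity, which left 9609 genes, 3682 of them with more than 1 detected probe. Where one side of a comparison was below background on all its arrays, the fold is given as "at least", the mean of the brighter side against the mean, per array, of the higher of the lowest signal among detected probes and the gene's own signal. No fold is given where both sides were below background.

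Mean probe intensity was 298 to 559 per array and 15322 to 17182 probes were detected. Across genes, the 4 normoxia arrays correlated at r = 0.996 to 0.997 though they held different transfections, while the 2 hypoxia replicates of 1 transfection correlated at 0.967 to 0.986. The number of arrays limits the precision.

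Tests used lmFit and eBayes of limma with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Hypoxia was compared with normoxia in a fit of transfection plus oxygen over the 12 arrays. The comparisons between transfections in hypoxia, the interaction, the hypoxia response within each transfection and the difference of responses came from a fit with a mean per group, in which a lone normoxia array is assumed to vary like the other groups. In normoxia no test was made. Values after ± are standard errors of log2 differences.

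Gene lists were fixed before the data were examined: HIF glycolysis genes, other HIF targets, the study's follow-up genes, HIF pathway regulators, neuroendocrine markers, FOXA2 endoderm and liver targets, epithelial and luminal genes, mesenchymal genes, cell cycle, cholesterol synthesis, amino acid and endoplasmic reticulum stress response, interferon-stimulated genes, immediate early and heat shock genes, oxidative phosphorylation, immune markers and endothelial markers. So were the comparisons, the tests and the rule for named genes. Lists with at least 3 measured members were tested with camera, with a preset correlation of 0.01 and with an estimated correlation. Lists of ribosome biogenesis, glycogen, Jumonji-domain, histone, circadian, p53 target, cornified envelope and YAP/TAZ target genes were added after seeing the data. The named genes were Foxa2, Hif1a, Hes6, Sox9 and Kdm3a, then up to 10 genes with the largest change in each direction among called genes whose arrays did not overlap, or, where fewer than 10 passed, the 5 with the smallest p in each direction, and the up to 4 members of each list with the smallest p. Unannotated transcripts were counted but not named. The text gives a part of these names, and names others where it says so or where a list is described by its members.

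Replicate numbers come from the sample labels. In hypoxia the deviations of same-numbered arrays from their group means correlated across genes in all 6 pairs of transfections, at 0.782 for control with FOXA2, 0.584 for control with HIF-1a, 0.490 for control with both, 0.560 for FOXA2 with HIF-1a, 0.514 for FOXA2 with both and 0.286 for HIF-1a with both. The numbers therefore pair the arrays, and a fit with the replicate number as a block was run beside each comparison.

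The procedure was tested on simulated data with 50 changed genes at each size. For hypoxia against normoxia it called 36%, 78%, 96% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, and 7 of 9409 unchanged genes. For FOXA2 against control it called 0%, 34%, 86% and 86%, and 10 unchanged genes. For both factors against control it called 0%, 20%, 88% and 88%, and 1 unchanged gene. The simulated noise was independent between arrays, whereas the same-numbered hypoxia arrays shared a difference. A planted set of changed genes also eases the adjusted threshold, so these shares do not give the power on the real arrays. There the transfected Foxa2 and Hif1a were themselves not called in hypoxia against control.

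Alternatives were no background correction, normexp with an offset of 50, median centring, the authors' processed values, no detection filter, detection on all 12 arrays, the mean of a gene's probes, eBayes with trend and robust, slide as a fixed or random block (duplicateCorrelation with statmod 1.5.0), the replicate block, other models, and leaving out each array in turn. Fits on slide 1 alone, on replicate 1 or replicate 2 hypoxia arrays alone, the additive fit with the replicate block, and gene lists without each array in turn were chosen after seeing the data.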

Results

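Gene expression was measured on 12 arrays of TRAMP-C cells, a line derived from the prostate tumour of a transgenic TRAMP mouse. Cells had been transfected with an empty pcDNA vector (control), with FOXA2, with HIF-1a or with both, and 48 h later were kept in normoxia or in 1% oxygen (hypoxia) for 12 h. Each of the 4 transfections had 1 normoxia array and 2 hypoxia arrays. FOXA2 is a forkhead transcription factor of endoderm and of neuroendocrine prostate tumours, and HIF-1a is the oxygen-regulated subunit of hypoxia-inducible factor. The study asked how these factors act together in hypoxia in neuroendocrine prostate tumour cells. Mean probe intensity was 298 to 559 per array, and 15322 to 17182 of 45281 probes were detected. The small number of arrays limits the precision. The arrays lay on 2 slides, and every normoxia array carried replicate number 1. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

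The transfected genes were at high level in the arrays labelled for them. In hypoxia, Foxa2 log2 intensity was 9.27 and 10.98 in the FOXA2 arrays and 10.30 and 10.46 in the FOXA2+HIF-1a arrays, against 6.14 to 6.46 in the control and HIF-1a arrays. In normoxia it was 9.96 with FOXA2 and 10.43 with both factors, against 7.07 in the control and 6.85 with HIF-1a. Hif1a log2 intensity was 11.98 to 13.18 in the 6 arrays transfected with HIF-1a and 9.06 to 9.64 in the other 6. Hes6, a neural transcription factor of the Hes family, lay between 6.86 and 7.17 in the normoxia arrays and between 7.93 and 9.14 in the hypoxia arrays. Sox9, a developmental transcription factor, lay between 9.40 and 9.63 in normoxia and between 11.33 and 11.87 in hypoxia. Kdm3a, a histone H3 lysine demethylase, lay between 9.54 and 9.74 in normoxia and between 11.30 and 11.82 in hypoxia.

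**Figure D1:**
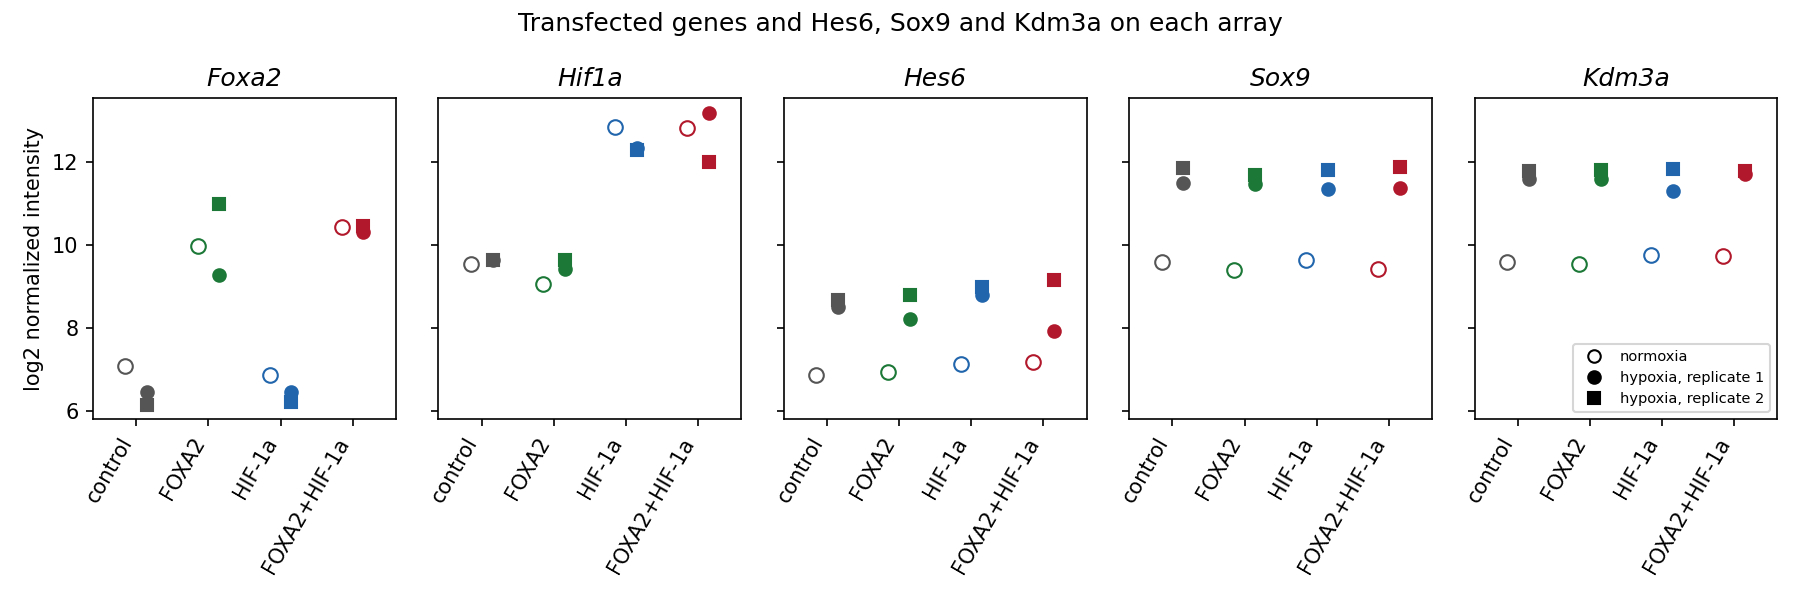
Log2 intensity (vertical axis) of Foxa2, Hif1a, Hes6, Sox9 and Kdm3a on each of the 12 arrays by transfection (horizontal axis), with open symbols for normoxia, filled circles for hypoxia replicate 1 and filled squares for hypoxia replicate 2. Foxa2 and Hif1a follow the transfection, while Hes6, Sox9 and Kdm3a lie higher on every hypoxia array than on any normoxia array.

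Hypoxia was compared with normoxia over the 4 transfections, 8 arrays against 4. The largest rises were in Mgarp, which encodes a mitochondrial protein, by log2 4.93 ± 0.26 (SE; 30.5-fold), and in Cdkn1a, the cyclin-dependent kinase inhibitor, by 4.83 ± 0.10 (28.5-fold; 3.14 to 4.29 on its other probes). Ankrd37, a known HIF target, rose by 4.71 ± 0.16 (26.1-fold) and Adm, the vasodilator peptide adrenomedullin, by 4.20 ± 0.15 (18.3-fold). Sox9 rose by 2.10 ± 0.13 (4.28-fold, adjusted p = 1.28e-06), Kdm3a by 2.01 ± 0.11 (4.04-fold, adjusted p = 5.49e-07) and Hes6 by 1.61 ± 0.20 (3.05-fold, adjusted p = 0.000213). The other detected Hes6 probes gave 0.86 to 0.95. Every normoxia array was replicate 1, and this fit had no replicate term. Each change therefore also holds part of the difference between the hypoxia replicates. Hes6 lay at 7.93 to 8.80 on the replicate 1 hypoxia arrays and at 8.67 to 9.14 on those of replicate 2. The level of Foxa2 differed by −0.29 ± 0.27 (adjusted p = 0.431) and that of Hif1a by −0.05 ± 0.21 (adjusted p = 0.878). Both values pool arrays of cells transfected with the gene and of cells without it. Without FOXA2, Foxa2 was 6.14 to 6.46 in hypoxia and 6.85 and 7.07 in normoxia. It was 9.27 and 10.98 against 9.96 with FOXA2 alone, and 10.30 and 10.46 against 10.43 with both factors.

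Other genes with large rises were Smtnl2 (4.03 ± 0.11, detected on 1 of 4 normoxia arrays), Zbtb8b (3.83 ± 0.16) and Stc1, the hormone stanniocalcin (3.67 ± 0.17). For genes below background on every normoxia array only a bound could be given. The galanin receptor gene Galr2 was at least 10.3-fold higher in hypoxia, the simple epithelial keratin Krt19 at least 9.63-fold and Espn, an actin-bundling protein, at least 7.8-fold. The largest decreases were in Prokr1, a prokineticin receptor (−1.97 ± 0.24, detected on 5 of 8 hypoxia arrays), Arsj (−1.89 ± 0.17), Slc11a2, a metal ion transporter (−1.80 ± 0.15), and Fjx1 (−1.71 ± 0.28). The other probes of Slc11a2 gave −0.65 to −0.18. Ydjc fell by 1.68 ± 0.16, Rasl11a by 1.55 ± 0.12 and the histone gene H1f2 by 1.58 ± 0.31. Atoh8 and Ppargc1b, a coactivator of mitochondrial genes, gave −1.62 ± 0.18 and −1.51 ± 0.15 and were each detected on 3 of 8 hypoxia arrays. Each of these genes was called at an adjusted p under 0.05, and within every transfection both hypoxia arrays lay on the same side of the normoxia array, as the rule for named genes required. Of all 2918 genes called, 2640 met that requirement.

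HIF target genes rose together in hypoxia. Of 29 measured HIF targets outside glycolysis, 27 rose, 0 fell and 2 did not pass (27 adjusted over the list alone), with a median log2 change of 2.10. Ndrg1 rose by 3.25 ± 0.18, the HIF prolyl hydroxylase Egln3 by 3.10 ± 0.12 (1.22 on its other probe), the carbonic anhydrase Car9 by 2.11 ± 0.19 and the angiogenic factor Vegfa by 1.73 ± 0.12, and Rora, a nuclear receptor, was at least 4.82-fold higher. Stc2 (0.06 ± 0.10) and Mif (−0.09 ± 0.10) were the 2 that did not pass. Of 16 measured glycolysis genes regulated by HIF, 14 rose, 1 fell and 1 did not pass (15 up and 1 down adjusted over the list alone). The phosphofructokinases Pfkp and Pfkl rose by 2.77 ± 0.11 and 2.13 ± 0.10 (0.84 on the other Pfkl probe), the pyruvate dehydrogenase kinase Pdk1 by 2.74 ± 0.19 and the glucose transporter Slc2a1 by 2.38 ± 0.10. Another glucose transporter, Slc2a3, fell by 0.43 ± 0.13, and Gapdh differed by 0.33 ± 0.14 and did not pass. The camera test called both lists with the preset correlation (adjusted p = 5.52e-28 and 4.02e-12) and with an estimated correlation (adjusted p = 0.00143 and 0.00579).

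The 3 follow-up genes of the study, Hes6, Sox9 and Kdm3a, all rose (3 adjusted over the list alone), and as they had been chosen by the study on these samples the list is not independent evidence. Its camera adjusted p was 6.79e-05, and adjusted p = 0.101 with an estimated correlation. Of 12 measured regulators of the HIF pathway, 1 rose, 0 fell and 11 did not pass (1 adjusted over the list alone). The ubiquitin ligase gene Siah2 rose by 1.25 ± 0.16, and the list as a whole was not called (adjusted p = 0.831), with a median of −0.002 and a mean of 0.16. Among other members the HIF-binding ligase component Vhl gave 1.43 ± 0.68 (adjusted p = 0.134) and Crebbp −0.46 ± 0.16 (adjusted p = 0.0513). Vhl log2 intensity was 6.05 on HIF-1a hypoxia replicate 1, 9.78 to 10.78 on the other hypoxia arrays and 8.37 to 8.59 on the normoxia arrays. Every hypoxia array but that 1 thus lay above the normoxia arrays.

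Genes of cholesterol synthesis were higher in hypoxia. Of 17 measured, 14 rose, 0 fell and 3 did not pass (15 adjusted over the list alone), with a median of 1.13. The lanosterol synthase Lss rose by 1.35 ± 0.18, the squalene epoxidase Sqle by 1.28 ± 0.14, Insig1, a regulator of sterol sensing, by 1.26 ± 0.17 and the sterol carrier Stard4 by 1.13 ± 0.11. The list was called by camera (adjusted p = 1.14e-08), with adjusted p = 0.204 with an estimated correlation. Its median was 0.86 with the slide as a block, 0.77 on slide 1 alone and 0.72 with the replicate number as a block.

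Of 26 measured genes of the amino acid and endoplasmic reticulum stress response, 8 rose, 1 fell and 17 did not pass (8 up and 1 down adjusted over the list alone). The lipoprotein receptor Vldlr rose by 2.12 ± 0.09, the pseudokinase Trib3 by 1.02 ± 0.16 and the transcription factor Xbp1 by 0.75 ± 0.11, while Chac1, a glutathione-degrading enzyme, fell by 0.73 ± 0.12. The list had a median of 0.22 (adjusted p = 0.00687), and adjusted p = 0.204 with an estimated correlation. Of 18 measured immediate early and heat shock genes, 7 rose, 1 fell and 10 did not pass (8 up and 1 down adjusted over the list alone). The haem oxygenase Hmox1 rose by 1.72 ± 0.11, the phosphatase Dusp1 by 1.21 ± 0.11 and Jun by 0.99 ± 0.15, while the transcription factor Egr1 fell by 1.14 ± 0.13. That list had a median of 0.23 (adjusted p = 0.0456), and adjusted p = 0.147 with an estimated correlation. It was not called without any 1 of the 4 replicate 1 hypoxia arrays or the normoxia array of the control or of FOXA2+HIF-1a (adjusted p = 0.0509 to 0.136).

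Of 27 measured cell cycle genes, 5 fell, 1 rose and 21 did not pass (5 down and 1 up adjusted over the list alone). The cyclin Ccnd1 fell by 0.71 ± 0.14, the mitotic activator Cdc20 by 0.68 ± 0.09 and the centromeric histone Cenpa by 0.43 ± 0.08, and the replication clamp Pcna rose by 0.45 ± 0.10. The other Cenpa probe gave −0.04, and the mean of the probes was not called (−0.24, adjusted p = 0.109). The median was −0.21 (adjusted p = 0.0104), with adjusted p = 0.204 with an estimated correlation. With the replicate number as a block the median was −0.13 and the list was not called (adjusted p = 0.0803).

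Of 27 neuroendocrine and neuronal markers only 5 were measured, of which 2 rose, 0 fell and 3 did not pass (2 adjusted over the list alone). Neuron-specific enolase Eno2 rose by 0.95 ± 0.20 and the adhesion molecule Ncam1 by 0.52 ± 0.12, whereas Scg5 (0.17) and Gap43 (−0.47, adjusted p = 0.205) did not pass. Gap43 was called lower with the replicate number as a block (−0.83, adjusted p = 0.0105). Of 30 endoderm and liver targets of FOXA2, 2 were measured, Krt19, which rose (1 adjusted over the list alone), and the transferrin gene Trf, which differed by −0.43 ± 0.48 (adjusted p = 0.541). Of 6 measured epithelial and prostate luminal genes, 1 rose, 1 fell and 4 did not pass (1 up and 1 down adjusted over the list alone). Klf5 rose by 0.70 ± 0.14 and the androgen-regulated chaperone Fkbp5 fell by 0.56 ± 0.11, while E-cadherin Cdh1 differed by 0.31 ± 0.39 and the keratin Krt8 by −0.27. Cdh1 was called lower with the replicate number as a block (−0.40, adjusted p = 0.0492), and the direction of Trf turned (0.46, adjusted p = 0.0507). Of 24 measured mesenchymal genes, 2 rose, 2 fell and 20 did not pass (0 adjusted over the list alone). The intermediate filament gene Vim rose by 0.60 ± 0.20 and the repressor Snai1 by 0.33 ± 0.11, while the matricellular protein Ccn1 fell by 1.38 ± 0.48 and the actin-binding protein Tagln by 0.96 ± 0.33. The calls on Snai1 and Tagln ended with the replicate number as a block (0.29 and −0.40, adjusted p = 0.0793 and 0.120), and those on Vim and Ccn1 with the slide as a block (0.64 and −0.72, adjusted p = 0.0538 and 0.0653). Ccn1 was −0.49 with the replicate block and Tagln −0.45 with the slide block, both called. All 4 calls also ended on leaving out any 1 of the 4 normoxia arrays (adjusted p = 0.0547 to 0.148). The neuroendocrine, epithelial and mesenchymal lists were not called by camera (adjusted p = 0.137, 0.889 and 0.871), and the median (0.08) and mean (−0.03) of the mesenchymal list differed in sign.

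Of 30 measured interferon-stimulated genes, 4 fell, 1 rose and 25 did not pass (3 down and 1 up adjusted over the list alone), and the list was not called (adjusted p = 0.180). Ifit2 fell by 0.81 ± 0.15 and Ifit3 by 0.66 ± 0.14 (−0.37 on its other probe). Stat2, a transducer of interferon signals, rose by 0.52 and lost its call with the replicate number as a block (0.36, adjusted p = 0.0824) and with the slide as a block (adjusted p = 0.0602). Without the normoxia array of FOXA2, HIF-1a or FOXA2+HIF-1a, or control hypoxia replicate 2, Stat2 was not called (adjusted p = 0.0502 to 0.116). Of 26 measured oxidative phosphorylation genes, 1 fell, 0 rose and 25 did not pass (0 adjusted over the list alone), with a median of 0.01 (adjusted p = 0.889). The cytochrome c gene Cycs fell by 0.47 ± 0.16, a call that ended with the replicate block (−0.21, adjusted p = 0.140) and without any 1 of the normoxia arrays or replicate 2 hypoxia arrays (adjusted p = 0.0675 to 0.149). Among markers of other cell types, 2 of 20 immune genes and 1 of 13 endothelial genes were measured, and each was called adjusted over the list alone as well. Csf1r, a macrophage receptor, was at least 1.27-fold higher, Cd14 rose by 0.45 ± 0.13 (0.36 and adjusted p = 0.0578 with the replicate number as a block) and the vascular receptor Flt1, which HIF can induce, rose by 1.09 ± 0.16. Without the normoxia array of the control or of FOXA2+HIF-1a, Csf1r (adjusted p = 0.0617 and 0.0776) and Cd14 (adjusted p = 0.0950 and 0.105) were not called.

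**Figure D2:**
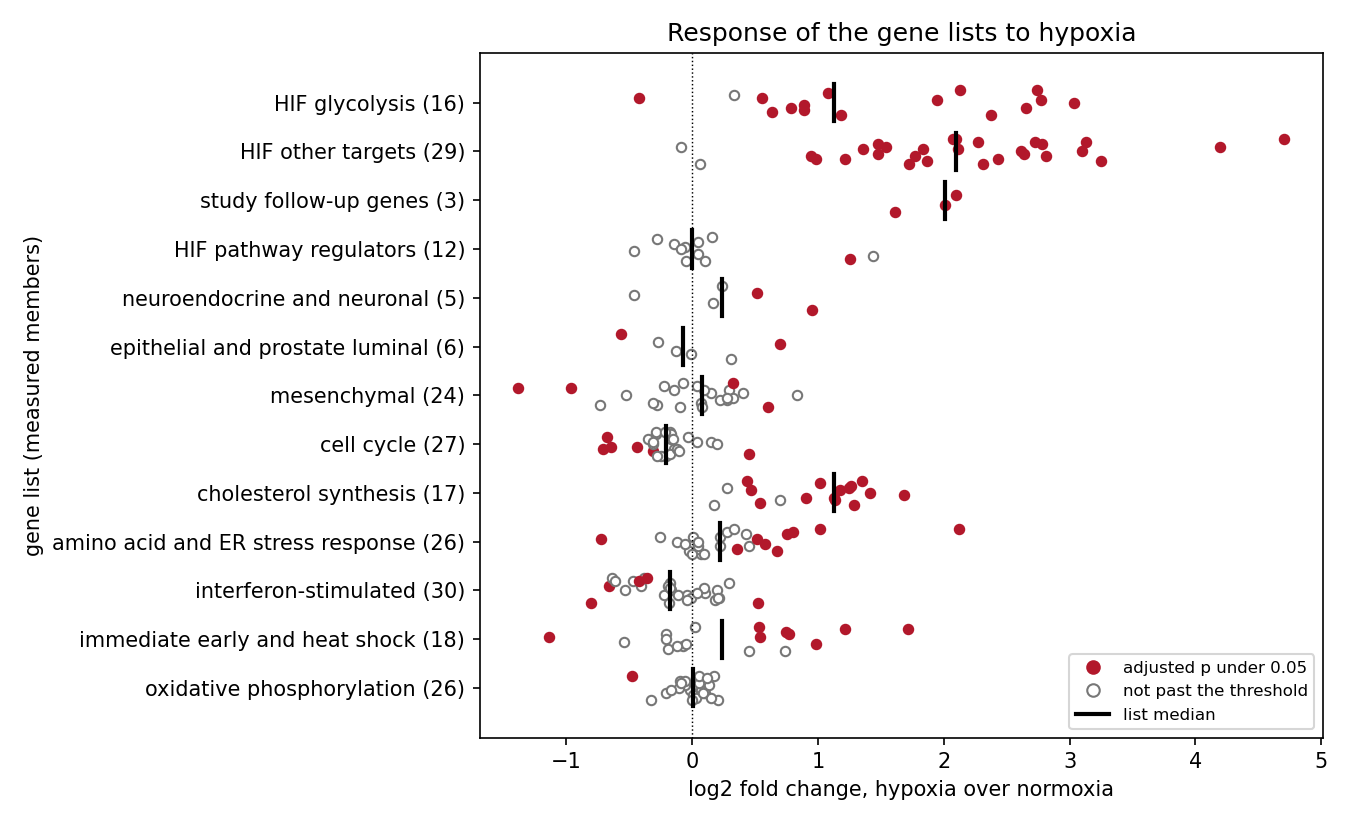
Log2 change between hypoxia and normoxia (horizontal axis) of each measured member of the 13 lists with at least 3 measured genes (vertical axis, spread for legibility only), with members at an adjusted p under 0.05 in red and a bar at each list's median. The medians of the HIF targets and HIF glycolysis genes were 2.10 and 1.13, and that of oxidative phosphorylation was 0.01.

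In all, 2918 of 9609 genes were called between hypoxia and normoxia, 1386 higher and 1532 lower, of which 301 higher and 117 lower by more than 2-fold. With the slide as a block 2716 genes were called, and on slide 1 alone, 3 arrays against 3, 2112. Slide 2 held 1 normoxia array, that of FOXA2+HIF-1a. Leaving out the normoxia array of FOXA2, HIF-1a or FOXA2+HIF-1a gave 1864, 1797 and 1917 genes. A fit with a mean per group gave 1628 genes, and replicate 2 hypoxia arrays alone against the normoxia arrays, all of replicate 1, gave 5082. Replicate 1 hypoxia arrays alone gave 2663 genes, 2168 of them among the 2918, and a fit with the replicate number as a block gave 2888, 2367 of them among the 2918.

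Each transfection was then taken alone, 2 hypoxia arrays against 1 normoxia array. Hypoxia raised 62 genes in control cells, 65 with FOXA2, 72 with HIF-1a and 57 with both, and lowered 1, 1, 1 and 2. The scarcity of decreases held for this fit: with the replicate number as a block 31 genes were called lower in control cells and 48 with FOXA2. In all 4 transfections 42 genes were called higher, out of 86 called higher in any. Mgarp rose by 5.39, 5.07, 5.05 and 4.21 in control, FOXA2, HIF-1a and FOXA2+HIF-1a cells, Cdkn1a by 4.75, 4.90, 4.76 and 4.92, and Ankrd37 by 5.05, 4.80, 4.42 and 4.56. Krt19 was at least 9.21-fold higher in each. Sox9 rose by 2.09, 2.17, 1.93 and 2.20 (each ± 0.32; adjusted p = 0.0386, 0.0332, 0.0478 and 0.0372), and Kdm3a by 1.82 to 2.14 (each ± 0.27). Hes6 differed by 1.73, 1.57, 1.78 and 1.37 (each ± 0.47) and did not pass (adjusted p = 0.281, 0.334, 0.191 and 0.293). Hes6 was called with HIF-1a when the replicate number was a block (1.51, adjusted p = 0.0498). The genes called lower in the fit without the block were Dus4l in control (−1.31 ± 0.21), FOXA2 and FOXA2+HIF-1a cells, Ydjc with HIF-1a (−2.26 ± 0.29) and Rasl11a with both factors (−1.84 ± 0.27).

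**Figure D3:**
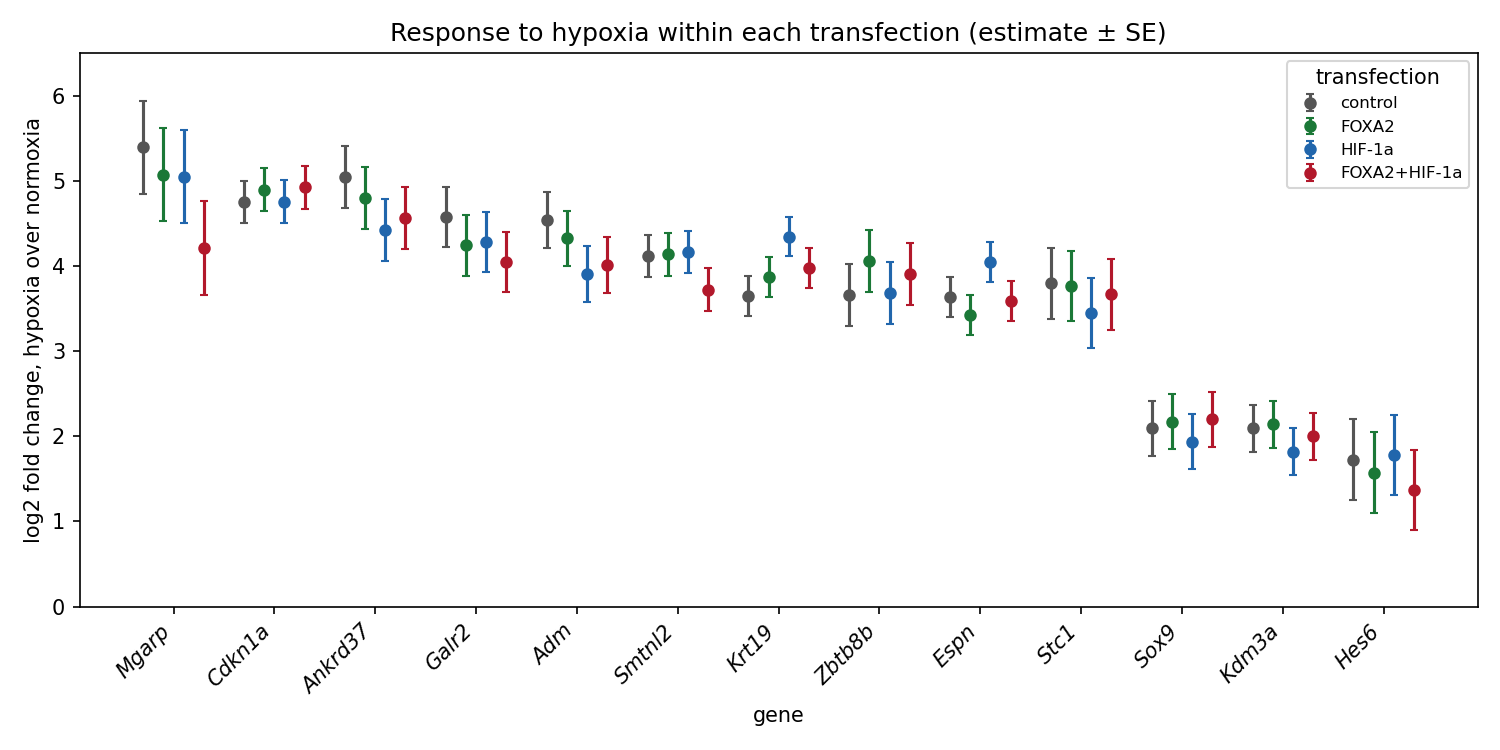
Fitted log2 change between hypoxia and normoxia (vertical axis) of 13 genes (horizontal axis) in each of the 4 transfections (colours), with bars of 1 SE from the fit with a mean per group; Galr2, Krt19 and Espn were below background in normoxia, as was Smtnl2 except with both factors, so their fitted values are no bounds. Cdkn1a lies between 4.75 and 4.92 and Sox9 between 1.93 and 2.20 in the 4 transfections.

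Of the 29 measured HIF targets outside glycolysis, 14, 16, 15 and 14 were called in control, FOXA2, HIF-1a and FOXA2+HIF-1a cells, and of the 16 glycolysis genes 4, 5, 4 and 3. Adjusted over the list alone these were 26, 26, 24 and 26 targets and 9, 10, 12 and 12 glycolysis genes. Both lists were called in every transfection also with an estimated correlation (adjusted p = 0.0130 to 0.0195 for the targets and 0.0193 to 0.0289 for glycolysis). The cholesterol synthesis list was called in each with the preset correlation though 0 members were (3, 5, 8 and 3 adjusted over the list alone), and gave adjusted p = 0.355 to 0.413 with an estimated correlation. The follow-up list, not independent evidence, had Sox9 and Kdm3a called in each (3 genes adjusted over the list alone) and adjusted p = 0.133 to 0.186 with an estimated correlation. The amino acid and endoplasmic reticulum stress list was called in each with 1 member called (1 adjusted over the list alone), and gave adjusted p = 0.359 to 0.413 with an estimated correlation. The cell cycle list was called lower in control and HIF-1a cells with 0 members called, also adjusted over the list alone (adjusted p = 0.359 and 0.413 with an estimated correlation). With the replicate number as a block neither the cell cycle list (adjusted p = 0.0898 and 0.109) nor the stress list (adjusted p = 0.0655 and 0.0645) was called in control and HIF-1a cells. The immediate early list was called in control, FOXA2 and FOXA2+HIF-1a cells with 0, 1 and 1 members called (2, 2 and 5 adjusted over the list alone), and gave adjusted p = 0.140 to 0.219 with an estimated correlation. The interferon list was called lower with both factors (adjusted p = 0.0186, and adjusted p = 0.439 with an estimated correlation), with 0 members called, also adjusted over the list alone, and there the antiviral membrane protein Bst2 gave −0.95 ± 0.23. Without 1 of its 2 hypoxia arrays the immediate early list was not called in any of these 3 transfections (replicate 1, adjusted p = 0.0766 to 0.195), the stress list in control and HIF-1a cells (replicate 2, adjusted p = 0.0946 and 0.359) or with both factors (replicate 1, adjusted p = 0.0915), the cell cycle list in HIF-1a cells (replicate 2, adjusted p = 0.187) or the interferon list with both factors (replicate 2, adjusted p = 0.287). Across genes the responses of pairs of transfections correlated at r = 0.782 to 0.909 (genes are not independent replicates), and pairs shared 45 to 59 calls, against 0.368 to 0.487 for independent lists. The responses share 1 estimate of the spread per gene, which favours the same genes in each, so independent lists are too low a reference. Each response also sets hypoxia arrays of both replicates against a replicate 1 normoxia array. The replicate difference that the transfections share thus enters all 4 responses and can raise the correlations and the shared calls.

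Leaving out hypoxia replicate 1 or 2 gave 15 and 12 genes in control, 32 and 18 with FOXA2, 40 and 112 with HIF-1a and 56 and 66 with both. Of the 112, 68 were at their lowest of the 12 arrays on HIF-1a hypoxia replicate 1. It ended the call on Sox9 in every transfection (adjusted p = 0.0814 to 0.253), except without FOXA2+HIF-1a hypoxia replicate 1, and on Kdm3a (adjusted p = 0.0546 to 0.147), except without HIF-1a hypoxia replicate 1. The calls on Dus4l ended without either replicate (adjusted p = 0.0659 to 0.366), as did that on Mgarp with both factors (adjusted p = 0.0746 and 0.0837), and those on Ydjc and Rasl11a ended without replicate 1. With median centring Sox9 was not called with HIF-1a (adjusted p = 0.0715) or with both factors (adjusted p = 0.0566), nor without a detection filter in control or HIF-1a cells. Dus4l was not called with median centring in FOXA2 or FOXA2+HIF-1a cells. With the trend and robust options of eBayes it was not called in these or in control cells. The replicate number as a block gave 215, 237, 321 and 262 genes in the 4 transfections. In FOXA2+HIF-1a cells, all on slide 2, the slide as a fixed or random block gave 156 and 123 genes, and in control cells a random block gave 99.

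With FOXA2 compared with the control in hypoxia, 2 arrays against 2, Foxa2 itself was 3.82 ± 0.48 higher on the log2 scale (adjusted p = 0.233), by 2.81 on slide 1 and 4.84 on slide 2. The next gene, Nckap1l, which encodes an actin regulator of blood cells, was at least 2.12-fold higher (adjusted p = 0.226), at least 2.35-fold on slide 1 and at least 1.91-fold on slide 2. The other genes with the smallest p did not pass either: Mep1a was at least 1.30-fold higher, the interferon gene Ifnb1 at least 1.27-fold lower, and Osbpl1a differed by −0.53 ± 0.18. limma called 0 of 9609 genes, with 21 at an unadjusted p under 0.05. About 480 would be expected by chance in this and each comparison between transfections below. With the replicate number as a block 83 were under 0.05 and 0 were called. The fit without the block takes the difference shared by same-numbered arrays into its error, so its 0 calls do not show that nothing changed. Mean levels with FOXA2 in hypoxia were 8.49 for Hes6, 11.57 for Sox9 and 11.68 for Kdm3a, against 8.59, 11.68 and 11.68 in the control. An additive fit over both oxygen levels, 3 arrays against 3, called Nckap1l (adjusted p = 0.000559) and Foxa2 (3.51 ± 0.35, adjusted p = 0.00355), and without FOXA2 hypoxia replicate 1 the fit with a mean per group called Foxa2 alone (4.68 ± 0.28).

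With HIF-1a compared with the control in hypoxia, 2 arrays against 2, Hif1a was 2.67 ± 0.35 higher (adjusted p = 0.671), by 2.70 on slide 1 and 2.63 on slide 2. Among the genes with the smallest p, the immunoproteasome subunit Psmb9 differed by 0.55 ± 0.17 and the lipase Mgll by 0.54 ± 0.19, and the helicase genes Ythdc2 and Ddx21 by −0.76 ± 0.22 and −1.50 ± 0.48. The prostaglandin synthase Ptgs2 differed by −1.70 ± 0.52. Without HIF-1a hypoxia replicate 1 Ddx21 and Ptgs2 differed by −0.74 and −0.99, and without replicate 2 Ddx21 differed by −2.26. None passed, and limma called 0 genes, with 82 at an unadjusted p under 0.05, or 360 with the replicate number as a block. Mean levels with HIF-1a were 8.89 for Hes6, 11.56 for Sox9 and 11.56 for Kdm3a. The additive fit over both oxygen levels called Hif1a (2.87 ± 0.28, adjusted p = 0.00457), and without HIF-1a hypoxia replicate 2 the fit with a mean per group called 69 genes, all lower. Of these, 68 were at their lowest of all 12 arrays on HIF-1a hypoxia replicate 1, the one HIF-1a hypoxia array left, 13 of them by more than 3 log2, and a local defect of that array was not tested.

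With both factors compared with the control in hypoxia, Foxa2 was 4.08 ± 0.48 and Hif1a 2.95 ± 0.35 higher, and Nckap1l was at least 1.95-fold higher (adjusted p = 0.130 each). On slide 2 Foxa2 and Hif1a differed by 4.24 and 2.94, and Nckap1l was at least 1.85-fold higher. Hes6 differed by −0.05 ± 0.39 (95% interval −0.95 to 0.84), Sox9 by −0.06 ± 0.26 (−0.67 to 0.54) and Kdm3a by 0.05 ± 0.22 (−0.47 to 0.57), and on slide 2 they differed by −0.14, −0.25 and −0.05. These intervals came from the fit without the replicate block, so the difference shared by same-numbered arrays widened them. In replicates 1 and 2, Sox9 was 11.36 and 11.87 with both factors against 11.50 and 11.86 in the control. Kdm3a was 11.70 and 11.77 against 11.57 and 11.78, and Hes6 7.93 and 9.14 against 8.51 and 8.67. Atxn2l was at least 2.38-fold and Nckap5l at least 1.48-fold higher, and the protease Sppl2a differed by −1.97 ± 0.39 (its other probes −0.64 to −0.42) and Csmd3 by −0.89 ± 0.22, none of which passed. limma called 0 genes, with 432 at an unadjusted p under 0.05, or 1099 with the replicate number as a block. With the replicate number as a block it called Foxa2, Hif1a and Nckap1l (adjusted p = 0.0368 each), as did the additive fit, and with median centring Hif1a (adjusted p = 0.0452). Without FOXA2+HIF-1a hypoxia replicate 2 it called 6 genes, all higher and all at their highest of the 12 arrays on replicate 1. Without replicate 1 it called 5, Hif1a higher and 4833420G17Rik, Map1lc3b, Pmp22 and Tm4sf1 lower, the last 4 named after their values were seen. All 4 were at their lowest of the 12 arrays on replicate 2, 2 of them by more than 3 log2, and a local defect of that array was not tested.

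The mesenchymal list was the one list called between both factors and the control (adjusted p = 0.0146), with a median of 0.19 and a mean of 0.26 and 0 of 24 members called, also adjusted over the list alone. Its values were adjusted p = 0.367 with an estimated correlation and, with median centring, a median of −0.004 and adjusted p = 0.146. Members with the smallest p included the growth factor Tgfb1, at least 1.55-fold higher, and the matrix genes Sparc (0.87 ± 0.28) and Col6a1 (0.72 ± 0.21). Tgfb1 log2 intensity was 6.43 and 5.45 in replicates 1 and 2 of FOXA2+HIF-1a. Without FOXA2+HIF-1a hypoxia replicate 1, the brightest of the 12 arrays (mean intensity 559), Sparc differed by 0.49 and Col6a1 by 0.54, and the list was not called (adjusted p = 0.405), nor was it without control hypoxia replicate 2 (adjusted p = 0.127). Without control hypoxia replicate 1 its median was 0.31.

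With both factors compared with FOXA2 alone, Hif1a was 3.05 ± 0.35 higher (adjusted p = 0.260; 2.94 on slide 2), Mllt10 at least 1.46-fold, and the deubiquitinase Usp5 and the transcription factor Elk3 differed by 1.07 ± 0.19 each. Grtp1 differed by −1.06 ± 0.22 and Uba6, a ubiquitin-activating enzyme, by −0.76 ± 0.17. limma called 0 genes, with 713 at an unadjusted p under 0.05, or 1567 with the replicate number as a block. The mesenchymal list was again called (adjusted p = 0.0371), with adjusted p = 0.480 with an estimated correlation and 0.128 with median centring, and it was not called without FOXA2+HIF-1a hypoxia replicate 1 (adjusted p = 0.468) or FOXA2 hypoxia replicate 2 (adjusted p = 0.0866). Median centring and the additive fit called Hif1a, and 5 or 15 genes were called without FOXA2+HIF-1a hypoxia replicate 1 or 2, of which 4 were at their lowest and 15 at their highest of the 12 arrays on the replicate left.

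With both factors compared with HIF-1a alone, Foxa2 was 4.04 ± 0.48 higher (adjusted p = 0.158; 4.16 on slide 2) and Nckap1l at least 1.96-fold. The integrin gene Itgav differed by 0.88 ± 0.18, and the receptor Notch4 and Bst2 by −0.97 ± 0.22 and −0.72 ± 0.19 (adjusted p = 0.185 for Bst2). limma called 0 genes, with 395 at an unadjusted p under 0.05, or 1055 with the replicate number as a block. With the replicate number as a block Nckap1l was called (adjusted p = 0.0455), and the additive fit called Foxa2 and Nckap1l. Without HIF-1a hypoxia replicate 2 there were 43 calls, 42 of them at their lowest of the 12 arrays on HIF-1a hypoxia replicate 1, and without FOXA2+HIF-1a hypoxia replicate 1 or 2 there were 4 and 7, at their lowest and highest on the replicate left.

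The interaction tested whether both factors together differed from the sum of each alone in hypoxia. Hes6 gave −0.26 ± 0.55 (95% interval −1.53 to 1.00), Sox9 0.16 ± 0.37 (−0.70 to 1.02) and Kdm3a 0.17 ± 0.32 (−0.57 to 0.90), each with an adjusted p of 1.00. These intervals too came from the fit without the replicate block. limma called 0 genes, with 243 at an unadjusted p under 0.05, or 720 with the replicate number as a block. Genes with the smallest p were the protease Furin (1.27 ± 0.29) and Tob2 (1.13) on the higher side and Hectd3 (−1.08) and Lgalsl (−1.30) on the lower side. Without HIF-1a hypoxia replicate 2 there were 19 calls, and without FOXA2+HIF-1a hypoxia replicate 1 there were 4, all 19 and all 4 at their lowest of the 12 arrays on the replicate left. Outside the mesenchymal list, camera called none of the fixed lists in these 6 comparisons. Adjusted over the list alone, the one member called in any list was the transfected Hif1a, among the HIF pathway regulators, in the 3 comparisons of HIF-1a cells with cells without it.

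The hypoxia response with both factors was set against that of the control, in the fit without the replicate block. The responses differed by −0.36 ± 0.67 for Hes6, 0.10 ± 0.46 for Sox9 and −0.09 ± 0.39 for Kdm3a (adjusted p = 1.00 each). limma called 0 genes, with 71 at an unadjusted p under 0.05, and 2 (4833420G17Rik and Map1lc3b, both lower) without FOXA2+HIF-1a hypoxia replicate 1. Nckap5l, below background in the control arrays, and Usp5 (1.23) had the smallest p on the higher side and Bst2 (−1.13) and Uba6 (−1.01) on the lower. The mesenchymal list was called higher (adjusted p = 0.0259), but not with an estimated correlation (adjusted p = 0.432), with median centring (0.0849), with the slide as a block (0.0944), without FOXA2+HIF-1a hypoxia replicate 1 (0.332) or without control hypoxia replicate 2 (0.111).

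In normoxia each transfection had 1 array, so differences have no replicate check. Against the control array, Foxa2 was 2.89 higher with FOXA2 and 3.36 with both factors, and Hif1a 3.28 higher with HIF-1a and 3.27 with both. Nckap1l, below background on the control array, was at least 2.2-fold higher with FOXA2 and at least 2.48-fold with both. Differences over 2-fold, with genes below background on the control array at their bound, were seen in 3, 3 and 4 genes, all higher, with FOXA2, HIF-1a and both factors. Hes6 differed by 0.06, 0.25 and 0.31, Sox9 by −0.18, 0.04 and −0.17 and Kdm3a by −0.04, 0.16 and 0.14.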

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

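The tests of the slide, of a stronger response, of a change by both factors, of the Nckap1l probe and of the brightness of FOXA2+HIF-1a hypoxia replicate 2 were chosen only after the result was seen. So was the comparison with other arrays in the test of replicate 1 brightness.

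Hypoxia replicate 2 differed from replicate 1 in 1581 genes, 811 higher and 770 lower, over the 4 transfections, and 1567 of them moved the same way in all 4 pairs. The test that called them used the same 4 pairs and favours genes whose pairs agree, so the 1567 are not independent evidence. The slide as the cause is argued against: in control, FOXA2 and HIF-1a the replicates lay on different slides, but in FOXA2+HIF-1a, on 1 slide, the median difference was still 0.83 of that in the others, over the 1913 genes called in those 3. A stronger hypoxia response in replicate 2, as the whole cause, would give nearly all these genes the direction of the replicate 1 response. Of the 1581 genes, 54.9% had it (mean of 6 splits of the transfections with no array in both difference and response, 52.3% to 57.8%). The genes themselves were chosen with all hypoxia arrays, those of replicate 1 with the opposite sign, which can lower the share. The share therefore argues against a stronger response as the whole cause only in as far as this choice did not lower it. As a part of the cause it stays open, with r = 0.114 to 0.159 across genes, which are not independent. A difference in culture state may contribute: 19 measured YAP/TAZ targets other than Ccn1 and Ccn2 had a median of −0.25, at percentile 0.12 of 10000 random lists matched on expression, with 14 of the 19 lower and 5 called lower, Fjx1 at −1.04 and Ankrd1 at −0.95 the furthest, and 0 called higher, Foxf2 at 0.33 the furthest. The list was added after the data were seen. Random lists do not carry the correlation among genes regulated together, and no test with an estimated correlation was made on it, so the percentile can be too extreme. Culture conditions are not in the labels, and culture, day and handling stay open.

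FOXA2+HIF-1a hypoxia replicate 1 was brighter than the 7 other hypoxia arrays: mean intensity 558.5 (others 298.5 to 378.4), median intensity 56.9 (40.4 to 44.6) and 17182 probes detected (15322 to 15995). Among its 200 genes furthest from the other hypoxia arrays, the shift in replicate 2 was 0.106 of that in replicate 1, which met the bound set beforehand for brightness as a cause. Replicate 1 arrays of usual brightness gave 0.142 (control), 0.18 (FOXA2) and −0.025 (HIF-1a), so the value, read as undecided for that reason after it was seen, does not separate a bright array from any single array, and brightness of replicate 1 stays open, as does its slide, which no other replicate 1 hypoxia array shared. A change by both factors as the whole cause is argued against, since over all genes the shifts of replicate 1 and replicate 2 correlated at r = 0.149, and as a part of it stays open. For replicate 2, which also stood apart, excess brightness is argued against by its mean intensity of 303.3, and loss of transcripts of long genes is argued against by a Spearman rho across genes of 0.0665 with genomic length. That mean and the mean of HIF-1a hypoxia replicate 1 (298.5) were the lowest of the 12 arrays, and low signal was not tested.

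Nckap1l was higher in every array with FOXA2 (6.17 to 6.52) than without it (4.43 to 4.83, below background). A probe that reads the FOXA2 construct is argued against, as the log2 slope of Nckap1l on Foxa2 over the 6 FOXA2 arrays was −0.0832 (95% interval −0.448 to 0.282) while Foxa2 ranged 3.7-fold. A response of Nckap1l to FOXA2 may be a biological explanation and stays open.

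The split of 8 hypoxia from 4 normoxia arrays called 2918 genes. Of 100 splits of the 12 arrays into 8 and 4, drawn out of 495 possible, 1 called as many, the real one, and the highest other drawn called 83. A random division of the arrays as the source of the count is argued against by the rank of the real split alone. The other splits had no term for oxygen, so the oxygen difference lay in their error and lowered their counts. Those counts do not estimate how many genes chance would call. The draw ignored the replicate numbers, so it does not exclude chance among paired arrays. The replicate numbers pair the arrays and all normoxia arrays are replicate 1: of 11 drawn splits with 4 replicate 1 arrays on the small side, the highest other called 0. A split of the 4 replicate 2 arrays from the other 8 called 2348. These 4 arrays were all in hypoxia, and the split had no term for oxygen. The count therefore cannot tell the replicate number from oxygen.

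Other values stood apart by the same test, which was made on 6 array measures (4 stood apart) and 146 gene series (8), with chance giving about 1 in 20. HIF-1a normoxia had 15642 probes detected (others 16099 to 16129). Ankrd37 in HIF-1a hypoxia 1 was 11.11 (11.62 to 12.05), Zbtb8b in FOXA2+HIF-1a hypoxia 2 10.61 (9.55 to 10.04), Crebbp in FOXA2 normoxia 6.197 (5.60 to 5.64) and Vhl in HIF-1a hypoxia 1 6.046 (9.78 to 10.78). Gap43 in HIF-1a hypoxia 1 was 5.051 (6.18 to 7.03), Vim in FOXA2+HIF-1a hypoxia 1 13.86 (12.49 to 12.99), Chac1 in FOXA2+HIF-1a hypoxia 2 11.11 (11.52 to 11.81) and Cd14 in the same array 9.561 (8.75 to 9.13). Among detected probes without a usable gene name, 522 of 2455 were called between hypoxia and normoxia, 228 higher and 294 lower, against 4106 of 14981 with a name.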

How the results depend on the processing

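Settings with slide 1 alone, with 1 hypoxia replicate alone, the additive fit with the replicate block and gene lists without 1 array were chosen only after the result was seen. Of 73 genes named for hypoxia against normoxia, 62 were called, 52 kept their call in every alternative and 0 of the called genes reversed. The hypoxia count was 1628 in the fit with a mean per group, 2663 and 5082 with replicate 1 or replicate 2 hypoxia arrays alone, 2888 with the replicate block (2367 shared with the 2918), and 1797 to 3300 on leaving out 1 array. Between transfections in hypoxia, where 0 were called, the additive fit, with or without the replicate block, called 2 genes for FOXA2 and 1 for HIF-1a against control, 3, 1 and 2 for both factors against control, FOXA2 and HIF-1a. The replicate block gave 3 and 1 for both factors against control and HIF-1a, and median centring 1 each against control and FOXA2. Leaving out 1 array gave 0 to 1, 0 to 69, 0 to 6, 0 to 15 and 0 to 43, 0 to 19 for the interaction and 0 to 2 for the difference of responses. For hypoxia within control, FOXA2, HIF-1a and FOXA2+HIF-1a cells the replicate block gave 215, 237, 321 and 262, a random slide block 99 in control and 123 with both factors, and a fixed slide block 156 with both. Leaving out 1 array gave 12 to 15, 18 to 32, 40 to 112 and 56 to 66. Among the genes and fixed lists named, the replicate block changed no other call than those given here and with the results.

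Genes near 0 changed sign. With hypoxia, Trf was 0.18 with the slide block, 0.46 with the replicate block and with replicate 1 alone and 0.32 on slide 1, and Cdh1 −0.13, −0.40, −0.40 and −0.31. Between both factors and control, Kdm3a was −0.039 with median centring, −0.10 with the slide block and −0.019 with a random slide block, and Hes6 0.25 with the mean of probes and 0.066 in both additive fits. In the interaction Hes6 was 0.28 with the mean of probes and Sox9 −0.016 with the slide block. In the difference of responses, the mean of probes gave 0.21 for Hes6 and 0.20 for Kdm3a, and the slide block 0.066 for Kdm3a. Leaving out 1 array gave −0.66 to 0.56, −0.32 to 0.19 and −0.053 to 0.16 for Hes6, Sox9 and Kdm3a against control, −0.87 to 0.35, −0.095 to 0.41 and −0.092 to 0.42 in the interaction, and −0.97 to 0.25, −0.15 to 0.36 and −0.20 to 0.017 in the difference. Leaving out an array leaves fewer samples; for the rest the cause was not tested. Signal over background limits genes near the detection floor to bounds.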

Other observations

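The tests of these gene lists were chosen only after the result was seen, as were all genes named here. Hypoxia lowered genes of ribosome biogenesis: 41 of 47 measured fell (43 adjusted over the list alone), with a median of −0.68, among them the RNA polymerase I subunit Polr1b (−1.25), Tsr1 (−1.10) and Bop1 (−0.82). The camera adjusted p was 1.51e-14, and adjusted p = 0.176 with an estimated correlation. With the replicate number as a block, 36 fell, the median was −0.52 and the adjusted p with an estimated correlation was 0.0132. Of 16 glycogen genes, 9 rose, with the glycogen-targeting phosphatase subunits Ppp1r3b and Ppp1r3c at 3.58 ± 0.12 and 3.53, Pgm1 at 1.80 and the branching enzyme Gbe1 at 1.44 (adjusted p = 2.4e-05, and adjusted p = 0.105 with an estimated correlation, or 0.0280 with the replicate block as well). Apart from Kdm3a and the HIF target Kdm4b (2.07), 15 listed Jumonji-domain genes were measured, of which 6 rose and 1 fell, with Jmjd6 at 1.26, Kdm7a at 1.07 and Kdm6b at 0.78 up and Riox1 at −0.47 (adjusted p = 0.0236, and adjusted p = 0.117 with an estimated correlation, or 0.0732 with the replicate block as well).

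Of 52 histone genes, 10 fell in hypoxia (4 adjusted over the list alone), with a median of −0.41, adjusted p = 4.0e-06 and adjusted p = 0.436 with an estimated correlation. In the replicate block fit 7 fell (1 adjusted over the list alone), with a median of −0.12, adjusted p = 0.0215 and adjusted p = 0.514 with an estimated correlation. Of 10 circadian genes, 4 rose and 2 fell, Ciart by 2.25, Per2 by 1.06 and Per1 by 0.92 upward and Nr1d2 at −0.82 (adjusted p = 0.0626, and 0.199 with the replicate block). Of 23 p53 target genes, 7 rose and 6 fell: Cdkn1a, Apaf1 (0.97) and Mdm2 (0.51) were higher while Plk2 (−0.98), Aen (−0.92) and Tigar (−0.91), each of the last 2 detected on 1 of 8 hypoxia arrays, were lower (adjusted p = 0.786, upward, with a median of −0.039). The replicate block gave 4 up and 8 down there, and turned the direction of the test downward (adjusted p = 0.924) with a median of 0.022. Of 18 cornified envelope genes, 2 rose and 0 fell (adjusted p = 0.786), or 4 and 1 with the replicate block (adjusted p = 0.488).

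Between the hypoxia replicates, 10 of 18 cornified envelope genes were lower in replicate 2 (adjusted p = 5.62e-06, and adjusted p = 0.276 with an estimated correlation), with Lce1g at −2.79, Sprr2h at −2.21 and Ivl at −1.99. Replicate 2 was lower for 30 of 52 histone genes (adjusted p = 1.5e-15, and adjusted p = 0.297 with an estimated correlation) and 16 of 47 ribosome biogenesis genes (adjusted p = 1.26e-09, and adjusted p = 0.276 with an estimated correlation). Of 17 cholesterol genes 10 were higher (adjusted p = 6.98e-08, and adjusted p = 0.297 with an estimated correlation), and Ly6c1 was 2.22, Cxcl2 1.93 and Cdh1 1.42 higher.

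On the HIF-1a hypoxia replicate 1 array, 13 genes lay more than 3 log2 below the lowest of the other 11 arrays, among them Erbin at 4.51 (9.42 to 9.99 elsewhere), Cox11 at 4.39 and Jak1 at 5.08, and on FOXA2+HIF-1a hypoxia replicate 2 there were 4, among them Tm4sf1 at 5.16. On the other arrays there were 0. Positions on the arrays were not used here, so a local defect of these 2 arrays stays open.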
